A study of Homo sapiens with 4 samples.

How the data were processed

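The 4 samples are HaCaT keratinocytes at low density (2 samples) and high density (2 samples), grown in DMEM with fetal bovine serum, per the labels' protocols. Total RNA from equal cell numbers was isolated with TRIzol and profiled with the nCounter miRNA assay, per the labels' protocols. The unit of the deposited values is a signal, which the authors made from barcode counts. The software, the normalization and any background correction are not given in the sources used here. What was done can be read in part from the deposited values. In each sample the 800 human miRNA probes and 5 mRNA probes were whole counts times one factor (1.07, 1.67, 1.05 and 1.52 for low density 1 and 2 and high density 1 and 2), and 100% of these values came out whole within 0.1 count. With those factors the geometric mean over the 805 probes was 23.7, 23.8, 23.7 and 23.8, so the scaling holds the mean of all probes, most of them near background, level between samples. A median change over all probes is therefore held near 0 by construction. The other probes, 6 negative controls, 6 positive controls and 5 plant or worm miRNAs, were deposited as unscaled counts and were multiplied by the sample's factor here before they were set beside the human probes.

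Each of the 822 probes had one value per sample, and 0 columns were left without a sample. The total deposited signal over human miRNA probes was 44335, 57136, 83163 and 65922 for low density 1 and 2 and high density 1 and 2. The positive controls collected 9865, 5667, 13957 and 4741 counts in the same order, so the samples numbered 1 were counted more deeply than those numbered 2. The background level of a sample was the mean + 2 SD of its negative controls, 19.0, 26.4, 26.0 and 12.9 in signal, and 433, 287, 220 and 600 human probes lay at or above it. The counts of the 2 samples of a density were compared to look for one library deposited under 2 names, and their chi-square per degree of freedom was 2.74 at low and 4.01 at high density, above counting noise. This does not show that the samples came from separate cultures. The correlation across the 435 tested probes was 0.912 between the low density samples, 0.952 between the high density samples and 0.906 to 0.918 between densities, and probes are not independent replicates.

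The comparison was high minus low density on log2(signal + 1), with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) and Benjamini-Hochberg adjustment over the 435 human probes that reached the background level in at least 2 of the 4 samples. The threshold was an adjusted p of 0.05. Fold changes are on the log2(signal + 1) scale, which understates the change of dim probes. Lists of miRNAs with at least 3 tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the 20 lists tested. The lists, the tests and most alternatives were chosen before the data were examined. The probes named are those past the threshold in each direction (at most 10, without overlap and with a mean of at least 100 in the higher group), the 10 with the highest mean, and the 2 brightest tested members of each list. Where fewer than 5 met the first part in a direction, the 5 with the smallest p in it were named. Other named probes were chosen after their values were seen. A probe named for several miRNAs binds them alike.

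The alternatives were pseudocounts of 10 and 0.5, no filter and a minimum mean of 100, 6 other scalings between samples (total, the 100 brightest probes, the median of tested probes, quantiles, mRNA probes and positive controls). They also included subtraction of the negative controls, eBayes without a trend, an adjusted p of 0.10, the sample number as a block, leaving out each sample, and count tests on the recovered counts with edgeR 4.0.16 and DESeq2 1.42.0. The median over probes with a mean of at least 100, edgeR with the deposited factors, a background level from the plant and worm probes and a crossed block were added after seeing the data. The test was checked on 10 simulated data sets with the real means and a dispersion of 0.0509, for this comparison of 2 against 2 samples with 200 of 800 probes changed. It recovered 29.7% of tested probes changed 2-fold and 91.8% of those changed 4-fold, or 52.9% and 100% of those with a mean of at least 100. In simulations without change it called 2 of 4236 tests and 1 of 195 lists. The simulated counts were drawn independently for each probe with the same dispersion for all, so they hold no shift shared by the probes of a sample. The real probes with a mean of at least 100 had such a shift (SD of the sample medians 0.37), so these rates need not hold for the real data. Neighbouring miRNA genes were found in a RefSeq table of the assembly GRCh38.p14, used only for names and neighbours, since no genome build applies to the deposited values. Figures were drawn with matplotlib 3.10.9.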

Results

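miRNA levels were measured in HaCaT cells, an immortalized human keratinocyte line, kept at low or at high cell density, with 2 samples at each density. The nanoString nCounter assay counts a colour barcode for each miRNA, without amplification, and RNA was taken from the same number of cells at both densities. The comparison asked how miRNA expression as a whole, and that of single miRNAs, differed between the densities. Human miRNA probes collected 41472 and 34288 counts in the low density samples and 78841 and 43395 counts in the high density samples. The deposited signal is these counts times one factor per sample. Of 800 human miRNA probes, 435 lay at or above the background level in at least 2 of the 4 samples and were tested. Nothing in the labels says that the 2 samples of a density came from separate cultures, so p-values here measure only the spread between these samples, which may be technical. In limma that spread was mostly pooled over probes of like signal (median prior degrees of freedom 126.5). A probe's p-value therefore depends little on the spread of its own replicates.

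Of the 10 brightest probes, 9 belonged to the miR-17/92 and miR-15/16 groups. The probe shared by miR-106a-5p and miR-17-5p had a mean signal of 5568 over the 4 samples, followed by miR-19b-3p at 3356, the probe shared by miR-20a-5p and miR-20b-5p at 2942, miR-15b-5p at 2936 and miR-92a-3p at 2735. miR-4454 had a mean signal of 2108, miR-19a-3p 1951, miR-25-3p 1576, miR-93-5p 1459 and miR-15a-5p 1414. None of these 10 probes passed the threshold. Their log2 fold changes, high minus low density, lay between 0.43 for miR-106a-5p/miR-17-5p and 1.5 for miR-25-3p with the deposited scaling. That of miR-106a-5p/miR-17-5p became -0.13 after scaling to the total and -0.25 to the 100 brightest probes. By quantiles miR-4454 had -0.49, miR-93-5p -0.31, miR-20a-5p/miR-20b-5p -0.11 and miR-92a-3p -0.053. miR-25-3p had a signal of 797 ± 79.4 at low and 2354 ± 946 at high density (SD, n = 2 each; limma adjusted p = 0.0987).

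At high density 5 miRNAs rose and 0 fell at an adjusted p under 0.05. miR-99a-5p, known to repress mTOR, had the largest rise, from a signal of 40.4 ± 8.8 to 162 ± 27.3 (SD, n = 2 each; log2 fold change 1.98, SE 0.43, limma adjusted p = 0.00444). miR-9-5p, best known from neural progenitors, rose from 60.2 ± 18.6 to 206 ± 24.9 (log2 fold change 1.79, adjusted p = 0.0288). miR-301a-3p, which shares its seed with the miR-130 family, rose from 74.0 ± 10.9 to 257 ± 69.1 (log2 fold change 1.76, adjusted p = 0.0339). miR-30d-5p rose from 20.8 ± 8.3 to 50.7 ± 2.9 (log2 fold change 1.30, adjusted p = 0.0436) and miR-593-3p from 19.7 ± 9.8 to 54.3 ± 38.1 (log2 fold change 1.30, adjusted p = 0.046). Both lay at or above the background level in only 1 of the 2 low density samples, so their folds are against a level near background. By the background level from the plant and worm probes, miR-99a-5p too was near background. It had 46.7 in low density sample 2, where that level was 51.9, while miR-9-5p had 73.3 and miR-301a-3p 81.7. miR-593-3p rested on high density sample 1, with a signal of 81.2, while high density sample 2 had 27.3 and low density sample 2 had 26.7. Its SE of 0.37 came mostly from probes of like signal, so its adjusted p hardly reflects the gap between its high density samples. The samples numbered 1 were counted more deeply than those numbered 2. Between the samples numbered 1 and between those numbered 2, the log2 fold change was 2.37 and 1.59 for miR-99a-5p, 2.23 and 1.35 for miR-9-5p, and 2.19 and 1.34 for miR-301a-3p. It was 1.75 and 0.84 for miR-30d-5p and 2.57 and 0.04 for miR-593-3p. With the sample number as a block 0 probes passed the threshold, and with the crossed block 54 did, though the labels name no pairs.

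**Figure D1:**
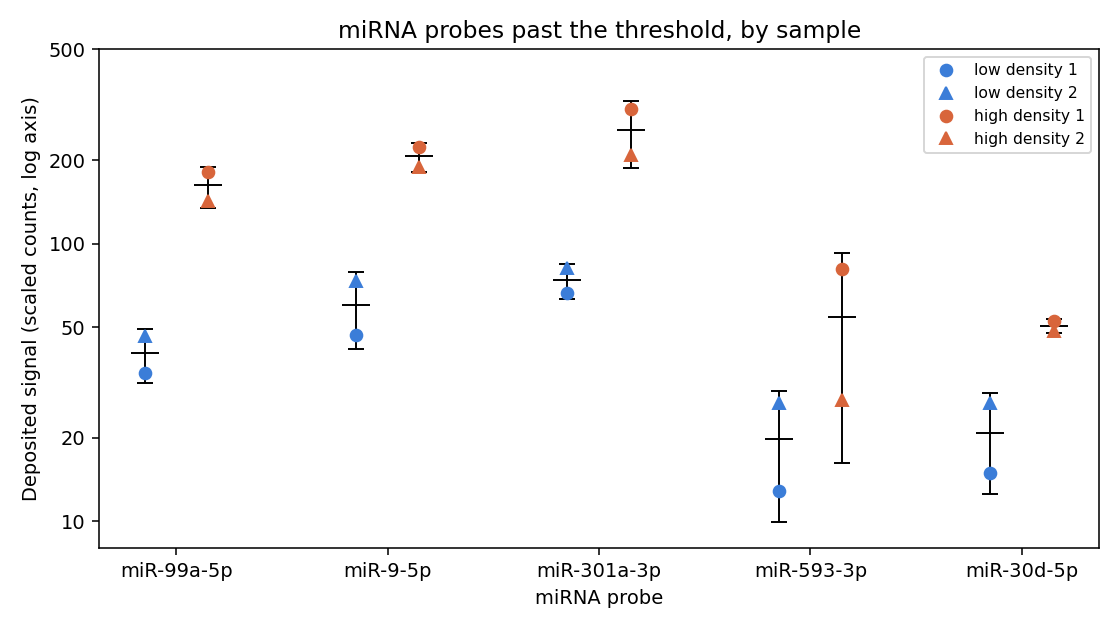
Deposited signal (scaled counts, log axis) of the 5 miRNA probes that passed the threshold, in each low density (blue) and high density (orange) sample, with circles for samples numbered 1, triangles for samples numbered 2, and black bars for the mean and SD of 2 samples. For miR-99a-5p both high density samples, at 181 and 143, lie above both low density samples, at 34.2 and 46.7, while for miR-593-3p high density sample 2, at 27.3, lies next to low density sample 2, at 26.7.

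No probe fell past the threshold in limma. At an unadjusted limma p under 0.05, 58 probes were higher and 11 lower, where 21.8 in all are expected by chance. Bright probes shifted together between replicates, so this count can lie far from 21.8 without any effect of density. On the recovered counts, edgeR with TMM called 4 higher and 2 lower, and DESeq2 called 25 higher and 1 lower. The 5 lower probes with the smallest p did not pass. miR-1253 had a log2 fold change of -1.15 (limma adjusted p = 0.0824), miR-548ak -1.06 (adjusted p = 0.0987), miR-767-3p -0.88 (adjusted p = 0.169) and miR-513a-3p -0.84 (adjusted p = 0.202). miR-1245b-5p had a signal of 34.6 ± 17.1 at low density and lay under the background level in both high density samples (12.4 ± 0.4, adjusted p = 0.0568). The split of calls depended on the scaling between samples, with 11 higher and 17 lower after scaling to the total and 8 and 33 after scaling to the 100 brightest probes. It was 0 and 2 after quantile normalization, 12 and 20 in edgeR with totals, 33 and 3 after scaling to the mRNA probes, 20 and 0 to the median of tested probes, and 0 and 0 to the positive controls. Of the 5 calls, 0 remained without low density sample 1, 5 without low density sample 2, 0 without high density sample 1 and 2 without high density sample 2.

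With the deposited scaling, which holds the mean of all probes level between samples, most bright miRNA probes were higher at high density. Among the 64 probes with a mean signal of at least 100, which include members of the miR-17/92, miR-15/16, let-7, miR-29, miR-148 and miR-221 groups, 60 were higher and 4 lower, with a median log2 fold change of 0.85, or 1.80-fold. miR-148a-3p had 449 ± 178 at low and 1284 ± 110 at high density (log2 fold change 1.57, adjusted p = 0.0824), and miR-16-5p 621 ± 121 and 1523 ± 626 (1.24, adjusted p = 0.202). miR-221-3p had 530 ± 120 and 1048 ± 177 (0.99, adjusted p = 0.314), and miR-21-5p 406 ± 59.9 and 480 ± 85.4 (0.24, but -0.32 after scaling to the total; adjusted p = 0.867). The 4 lower probes, named after their values were seen, were miR-378e at -0.63, miR-3676-3p at -0.66, miR-1283 at -0.76 and miR-1246 at -1.02, and none passed the threshold. Both high density samples lay above both low density samples for 45 of the 64 probes and below them for 2. For a single probe chance gives 33.3% for both directions together. The 64 probes shifted together between replicates (SD of the sample medians 0.37), so they are not independent and their share is no test. The other 371 tested probes had a median of -0.12, and all 435 a median of -0.005, with 216 higher and 219 lower, values that this scaling holds near 0.

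The median over the 64 bright probes was above 0 in every pairing of a high with a low density sample, but its size differed. It was 1.27 between the samples numbered 1, 0.33 between those numbered 2, 0.83 for high density 1 minus low density 2 and 0.93 for high density 2 minus low density 1. Replicates of one density differed by 0.52 (low density 2 minus 1) and 0.42 (high density 1 minus 2), and the SD of the sample medians was 0.37. An exact permutation test of 2 against 2 samples cannot go below a two-sided p of 0.333. The median was 0.65 after scaling to the 5 mRNA probes and 0.74 after scaling to the positive controls. It was 0.355 without ACTB and 0.813 without RPLP0 among the mRNA probes, the lowest and highest with 1 of them left out. It was 0.30 (42 higher, 22 lower) after scaling to the total, 0.18 (38 and 26) to the 100 brightest probes and 0.10 (33 and 31) by quantiles, scalings that themselves hold bright probes level between samples.

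**Figure D2:**
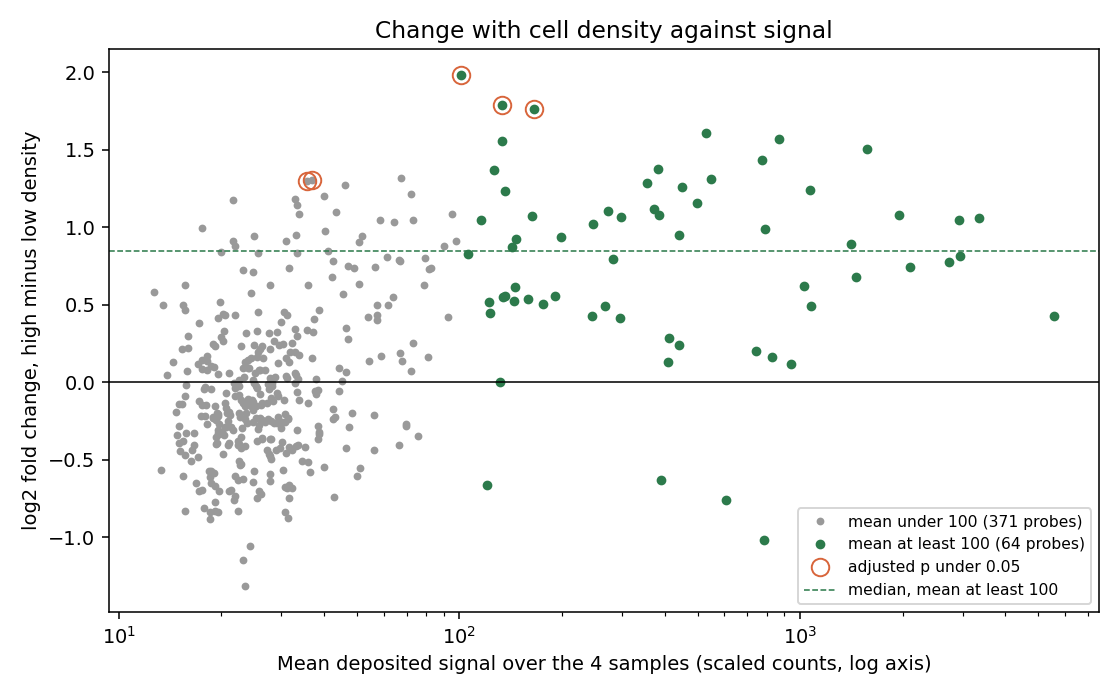
Log2 fold change, high minus low density, against the mean deposited signal over the 4 samples (scaled counts, log axis) for the 435 tested probes, with the 64 probes of mean at least 100 in green, the other 371 in grey and the 5 probes past the threshold circled. Most green points lie above 0, with 60 higher and 4 lower and a median of 0.85 (dashed line), while the grey points have a median of -0.12.

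Of 22 miRNA lists fixed before the data were examined, 20 had at least 3 tested members. By camera with a preset correlation, 4 were higher at high density than the other tested probes, most of which were dim. The preset of 0.01 treats members as nearly independent, while the estimated correlations of these 4 lists ran from 0.15 to 0.9. The preset p-values therefore take little account of a shift shared by the probes of a sample. The list of the miR-130, miR-301, miR-148 and miR-152 families had 7 of 7 tested members higher, with a median log2 fold change of 1.04 (camera adjusted p = 9.29e-05; adjusted p = 0.644 with an estimated correlation). Within them miR-301a-3p passed over all probes and 6 members passed adjusted over the list alone, with miR-148b-3p at 1.28 and miR-130b-3p at 1.04. The miR-30 family had 5 of 5 members higher, with a median of 1.05 (camera adjusted p = 0.000845; adjusted p = 0.644 with an estimated correlation). In it miR-30d-5p passed over all probes and 5 members passed adjusted over the list alone, among them miR-30b-5p with 272 ± 105 at low and 627 ± 11.2 at high density and miR-30e-5p with 47.9 ± 19.4 and 98.3 ± 29.5. None of the 4 lists passed with an estimated correlation, where the lowest camera adjusted p was 0.644. With 4 samples that test has few degrees of freedom, so it had little chance of passing after adjustment. For the 14q32 list, whose estimated correlation of 0.0125 is near the preset 0.01, the unadjusted camera p rose from 0.0246 to 0.157. The lack of calls there therefore does not decide whether these lists changed. The fry test asks whether a list's members move on balance one way, without setting them against other probes. Its lowest adjusted p was 0.256, and this test too is limited by the 4 samples. The median of the miR-130, miR-301, miR-148 and miR-152 list became 0.49 after scaling to the total and 0.37 to the 100 brightest probes. That of the miR-30 list became 0.50 and 0.38.

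The keratinocyte list, of miRNAs abundant in keratinocytes or rising as they differentiate, had 6 tested members, all higher, with a median of 0.85 (camera adjusted p = 0.00587; adjusted p = 0.644 with an estimated correlation). In it 0 members passed over all probes and 1 passed adjusted over the list alone, miR-210, a miRNA induced by low oxygen, with 26.5 ± 2.6 at low and 65.5 ± 8.8 at high density (log2 fold change 1.27). miR-26a-5p had a log2 fold change of 1.07 and miR-27b-3p 0.92. The list's best known members, miR-203, miR-205-5p and miR-184, were not tested (mean signals of 17.8, 13.7 and 15.9). None of them reached the background level in 2 of the 4 samples. miR-23b-3p, miR-24-3p and miR-27b-3p are also in the miR-23/27/24 list, which did not pass (camera adjusted p = 0.061), so these lists overlap. The keratinocyte list's median became 0.30 after scaling to the total, 0.18 to the 100 brightest probes and 0.39 by quantiles. The miR-17/92 and paralogous clusters had 9 of 9 tested members higher, with a median of 0.82 that became 0 after quantile normalization (camera adjusted p = 0.00587; adjusted p = 0.644 with an estimated correlation). In it 0 members passed over all probes and 2 passed adjusted over the list alone. The list's median was 0.26 after scaling to the total and 0.14 to the 100 brightest probes. Among the 64 bright probes alone, 5 lists had enough members and 0 were called, with a lowest camera adjusted p of 0.134. Of the 4 called lists, this test could be made only for the miR-17/92 list and that of the miR-130, miR-301, miR-148 and miR-152 families.

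**Figure D3:**
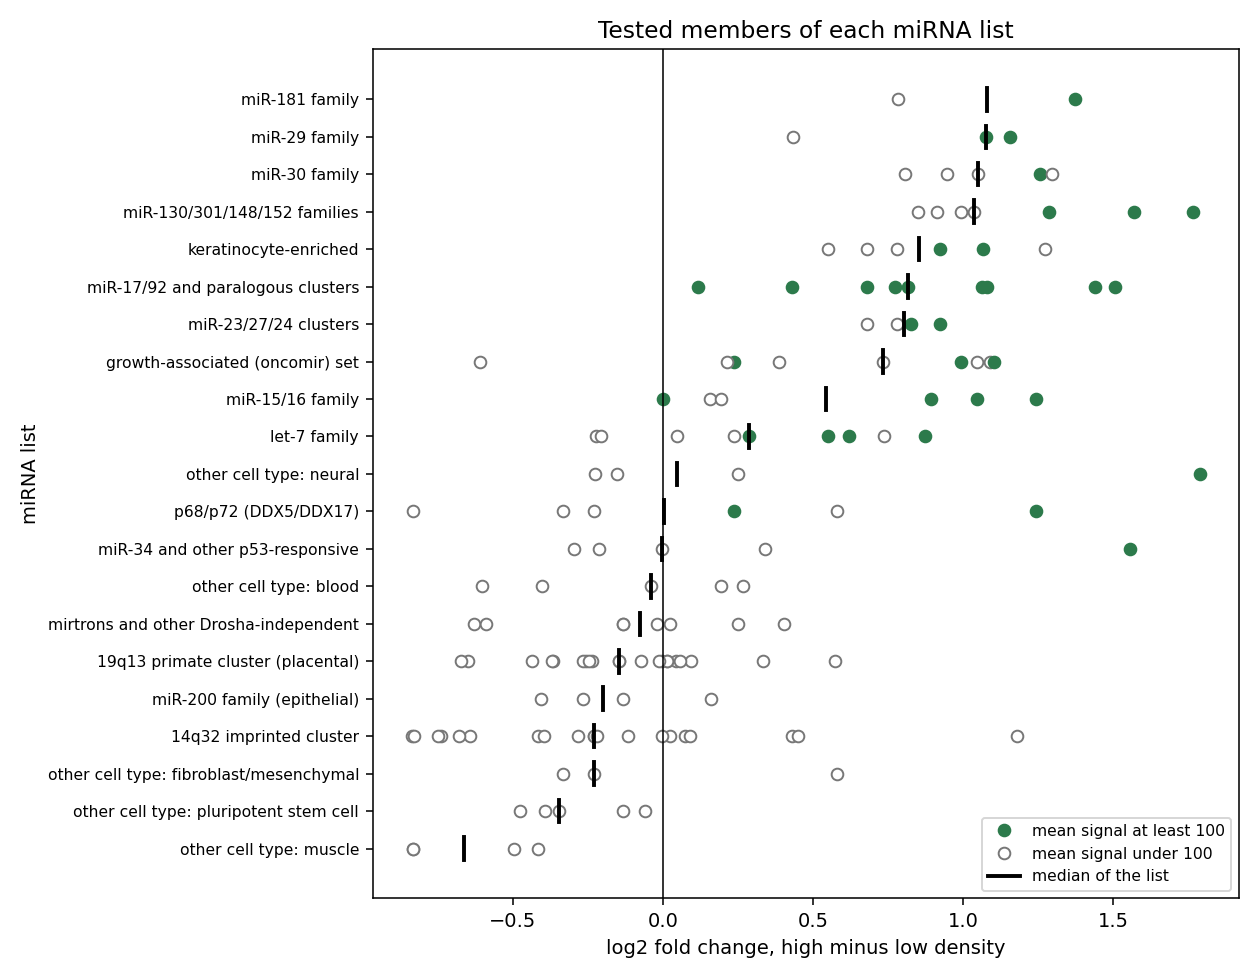
Log2 fold change, high minus low density, of the tested members of each miRNA list, with filled points for members of mean signal at least 100, open points for dimmer members and a bar at the list's median. The list of the miR-130, miR-301, miR-148 and miR-152 families and the miR-30 list lie wholly above 0, with medians of 1.04 and 1.05, while the miR-200 family and the lists of other cell types hold mostly dim members around or below 0.

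The other 16 tested lists did not pass. The miR-29 family had a median of 1.07 with 0 members passed over all probes and 2 adjusted over the list alone (camera adjusted p = 0.0801). The miR-23/27/24 clusters had a median of 0.80 (camera adjusted p = 0.061). The growth-associated set had 0.73 (camera adjusted p = 0.0616), with miR-222-3p at 1.10 and miR-21-5p at 0.24. After scaling to the total and to the 100 brightest probes the miR-29 median was 0.52 and 0.40. The miR-23/27/24 median was then 0.25 and 0.14, and the growth-associated median 0.18 and 0.066. The miR-15/16 family had a median of 0.54 that became -0.004 after scaling to the total and -0.12 to the 100 brightest probes (adjusted p = 0.156). The let-7 family, whose members restrain growth genes, had a median of 0.29 that became -0.27 and -0.39 after the same scalings (adjusted p = 0.415). Of the p53-responsive list miR-34a-5p had 69.3 ± 31.5 at low and 198 ± 48.1 at high density (log2 fold change 1.56, limma adjusted p = 0.0541). In that list 1 member passed adjusted over the list alone, the median was -0.004, the mean 0.28, the direction in camera higher and its adjusted p 0.59. The list of miRNAs whose processing uses the helicases p68 and p72 had a median of 0.003, a mean of 0.11 and a lower direction in camera, with only miR-16-5p and miR-21-5p at a mean of at least 100 (adjusted p = 0.914). The mirtrons and other Drosha-independent miRNAs, of which miR-484 was the brightest at a mean of 57.2, had a median of -0.076 (adjusted p = 0.455). The miR-181 family had 2 tested members, too few for the list test. Both passed adjusted over the list alone, miR-181a-5p with a log2 fold change of 1.37 and miR-181b-5p/miR-181d with 0.78. An adjustment over so few members changes the p-values little. The family's median of 1.08 became 0.53 after scaling to the total and 0.41 to the 100 brightest probes.

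miRNAs of the miR-200 family, typical of epithelia, stayed near background at both densities. miR-141-3p was the brightest at a mean signal of 29.1, and the list median was -0.20 (camera adjusted p = 0.537). The cause of these low signals in a keratinocyte line was not tested. Apart from miR-9-5p, no tested member of the lists of other cell types had a mean signal of at least 100, and the medians of the neural, blood, p53-responsive, helicase and mirtron lists changed sign with the scaling. The neural list had a median of 0.048 and a mean of 0.41, with miR-9-5p the 1 member passed over all probes and adjusted over the list alone and miR-128 at 0.25 (camera adjusted p = 0.455). The fibroblast list had a median of -0.23 and a mean of 0.005 with a lower direction in camera (adjusted p = 0.59). The blood list had a median of -0.039 (adjusted p = 0.618), the muscle list -0.66 (adjusted p = 0.0616) and the pluripotent stem cell list -0.35 (adjusted p = 0.236), in which miR-302d-3p had the highest mean, 75.7. The 14q32 imprinted cluster had a median of -0.23 (adjusted p = 0.0616) and the placental 19q13 cluster -0.15 (adjusted p = 0.21), with highest means of 42.8 and 35.7. The liver miRNA miR-122-5p, with a mean of 11.9, was not tested.

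The 5 mRNA probes read as controls moved in different directions. ACTB, cytoskeletal actin, had a signal of 429 ± 149 at low and 209 ± 35.6 at high density (log2 difference -1.0), and both high density samples lay below both low density samples. The ribosomal protein mRNA RPL19 had 1049 ± 199 and 1862 ± 668 (0.79), without overlap. RPLP0, also of a ribosomal protein, had 1662 ± 364 and 2982 ± 622 (0.84), also without overlap. After scaling to the total these differences were 0.24 for RPL19 and 0.29 for RPLP0, and to the 100 brightest probes 0.12 and 0.17. GAPDH had 1031 ± 90 and 1080 ± 288 (0.044) and B2M 197 ± 42.3 and 243 ± 39.2 (0.31). The sign of both flipped after scaling to the total (-0.51 and -0.24) and to the 100 brightest probes, and that of GAPDH also after scaling to the mRNA probes (-0.16) and positive controls (-0.067). The mRNA probes were not tested.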

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

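The test in this part was chosen after the result was seen. A rice miRNA probe, osa-miR442, lay at or above the negative control level in 4 of 4 samples, with a mean signal of 35.1, although human cells hold no such miRNA. Its signal was 36.4 ± 12.2 at low and 33.8 ± 13.4 at high density (SD, n = 2 each). A candidate explanation is a probe background above the negative controls: the median human miRNA probe lay nearer to the mean of the 4 other plant and worm probes than to that of the negative controls in 4 of 4 samples. osa-miR442 also lay above the highest of those other probes in 3 of 4 samples, which a level common to such probes leaves unexplained. The explanation stays open, and with it which of the dim tested probes, such as miR-141-3p at a mean of 29.1, are above their own background. With a background level from all 5 plant and worm probes, osa-miR442 among them, 167 probes were tested and 17 passed the threshold. No biological explanation was tested.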

How the results depend on the processing

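The count of 5 probes past the threshold changed with the scaling between samples, among other settings. It was 28 (11 higher, 17 lower) after scaling to the total, 41 (8 and 33) to the 100 brightest probes, 20 (20 and 0) to the median of tested probes, 2 (0 and 2) by quantiles, 36 (33 and 3) to the mRNA probes and 0 to the positive controls. It was 3 with a pseudocount of 10, 10 among the 64 probes of mean at least 100, 3 without a trend, 22 at an adjusted p of 0.10, 32 (12 and 20) in edgeR with totals, 26 (25 and 1, of 73 probes with an adjusted p) in DESeq2 and, added after seeing the data, 17 with the plant and worm filter. Leaving out 1 sample gave 1 to 8 calls, 1 without high density sample 1 and 8 without low density sample 2, and the lone sample of a density was then assumed to vary like the others. The labels do not say that the sample numbers mark pairs, and the deviations of same-numbered samples correlated at -0.20 over the tested probes and 0.59 over the bright ones. The replicate block gave 0 calls and 3 lists, and the crossed replicate block, added after seeing the data, 54 calls (49 and 5) and 5 lists. None of the 5 called miRNAs reversed, and miR-99a-5p passed under 18 of 23 alternatives, miR-9-5p and miR-301a-3p under 17 of 23, miR-593-3p under 8 of 21 and miR-30d-5p under 6 of 22.

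The median over tested probes, -0.005, moved to 0.85 with a minimum mean of 100 and to -0.54, -0.65, 0.096, -0.19 and -0.11 after scaling to the total, the 100 brightest probes, the median of tested probes, the mRNA probes and the positive controls. It moved to 0.087 after background subtraction, -0.18 and -0.60 in edgeR with TMM and with totals, and 0.50 with the plant and worm filter. The median over the 64 bright probes, 0.85, a summary added after seeing the data, moved to 0.30 after scaling to the total, 0.18 to the 100 brightest probes, 0.10 by quantiles and 0.30 in edgeR with totals. It ranged from 0.58 to 1.09 with 1 sample left out. The 4 lists past the threshold became 8 without a filter, 0 among the 64 bright probes (where 5 lists, 2 of these 4 among them, could be tested), 2 by quantiles, 7 after scaling to the positive controls, 9 at an adjusted p of 0.10, 8 in DESeq2, 7 in edgeR with the deposited factors (added after seeing the data) and 2 with the plant and worm filter, and 1 (without low density sample 1) to 9 (without high density sample 2) with 1 sample left out. The filters test fewer probes by construction, and scaling to the total, the brightest probes or quantiles holds bright probes level; for the other settings the cause was not tested.

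Reversals were looked for only among the 55 probes picked by the naming rule, and those found belonged to probes that had not passed. Others reversed too: over all 435 tested probes the number higher fell from 216 to 95 after scaling to the total and in edgeR with totals, and to 82 to the 100 brightest probes. Among the 55, those reversed after scaling to the total were let-7g-5p -0.27, miR-106a-5p/miR-17-5p -0.13, miR-1226-3p -0.29, miR-128 -0.30, miR-21-5p -0.32, miR-484 -0.14, miR-486-3p -0.27 and miR-520d-5p/miR-518a-5p/miR-527 -0.21. After scaling to the 100 brightest probes the same 8 were, in that order, -0.39, -0.25, -0.40, -0.42, -0.44, -0.26, -0.38 and -0.32, with let-7a-5p at -0.055. In edgeR with totals they were -0.26, -0.13, -0.31, -0.32, -0.36, -0.12, -0.29 and -0.20. By quantiles let-7g-5p was -0.45, miR-128 -0.28, miR-20a-5p/miR-20b-5p -0.11, miR-21-5p -0.51, miR-4454 -0.49, miR-92a-3p -0.053 and miR-93-5p -0.31. With 1 sample left out let-7g-5p ranged from -0.036 to 0.61, miR-1226-3p from -0.031 to 0.53, miR-128 from -0.18 to 0.68, miR-144-3p from -1.03 to 0.23, miR-192-5p from -0.54 to 0.12, miR-199a-5p from -0.94 to 0.27, and miR-200a-3p from -0.67 to 0.40. In the same way miR-302d-3p ranged from -0.72 to 0.024, miR-337-3p from -0.64 to 0.074, miR-371a-3p from -0.57 to 0.30 and miR-518b from -0.68 to 0.21. Of the 64 bright probes 4 were lower with all samples, and 9 were lower without low density sample 1 or without high density sample 1, so reversals were not limited to dim probes. The cause of these was not tested. At this depth 371 of the 435 tested probes had a mean signal under 100.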

Other observations

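The tests in this part were chosen after the results were seen. Members of one miRNA cluster, which are cut from a shared primary transcript, differed in their log2 fold changes with density. In the miR-17/92 cluster miR-18a-5p had 0.12, miR-106a-5p/miR-17-5p 0.43, miR-92a-3p 0.77, miR-19b-3p 1.06 and miR-19a-3p 1.08. The log2 ratio of miR-19b-3p to miR-18a-5p was 1.26 ± 0.039 at low and 2.21 ± 0.077 at high density (SD, n = 2 each). In the miR-106b/25 cluster miR-106b-5p had 1.44 and miR-25-3p 1.5 against 0.68 for miR-93-5p. The log2 ratio of miR-25-3p to miR-93-5p was -0.46 ± 0.086 at low and 0.37 ± 0.027 at high density. Such ratios within a sample do not move with a single scaling factor, apart from the pseudocount. In the miR-99b/let-7e/125a cluster miR-125a-5p had 1.61 against 0.54 for miR-99b-5p, and miR-450a-5p had 1.02 against 0.00 for its neighbour miR-503. For both pairs the change in the log2 ratio, 1.07 and 1.02, was larger than its spread between replicates. The SDs of the ratio at low and high density were 0.326 and 0.152 for the first pair and 0.031 and 0.099 for the second. They were 0.264 and 0.01 for miR-19a-3p to miR-18a-5p, and 0.08 and 0.234 for miR-106b-5p to miR-93-5p. Some pairs were thus noisier than the 2 whose ratios are printed with SDs above. All of these pairs were chosen for their size, and miR-19b-3p and miR-92a-3p are also cut from a paralogous cluster, which the probes cannot separate. The probe of miR-17-5p likewise reads miR-106a-5p, which comes from a paralogous cluster.

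The hypothesis that neighbouring miRNA genes changed alike through shared primary transcripts was tested over the 64 bright probes, of which 62 matched a RefSeq gene of GRCh38.p14. The 27 pairs of probes whose genes lie within 10 kb had a median absolute difference in log2 fold change of 0.35, against a mean of 0.53 for shuffled probes (one-sided permutation p = 0.0846, 100000 shuffles). Without pairs that share a miRNA number, such as miR-19a and miR-19b, 24 pairs had a median of 0.37 (one-sided permutation p = 0.12). The hypothesis did not pass at 0.05 and stays open.

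The higher level of bright probes at high density, with a median of 0.85 over 64 probes, is the pattern that most bears on the comparison. One candidate explanation is the authors' scaling to the mean of all probes, most of which lie near background. The lowest median under scaling to mRNA probes or positive controls was 0.653, under the mRNA scaling, with an SD of the sample medians of 0.061. That value depended on ACTB, without which it was 0.355. Under the positive control scaling the median was 0.739 with an SD of 0.434, which is too wide to exclude this explanation. Another is more RNA per lane at high density: set against each of the 5 mRNA probes alone, the median exceeded 0 by more than 2 SDs for 3 (ACTB, B2M and GAPDH) but was 0.064 against RPL19 and 0.012 against RPLP0. Which mRNA holds a constant level per cell at both densities was not tested, so a rise of miRNAs per cell at high density and a difference in RNA input stay open beside each other.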
